A study of Mus musculus with 11 samples.

How the data were processed

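Gene expression was measured in small intestinal villi of C57Bl/6J mice aged 5 months on Illumina bead arrays, 1 array per sample. The Villin-Gremlin mice carry a transgene that puts Gremlin, a secreted antagonist of bone morphogenetic proteins (BMPs), under the Villin promoter of the intestinal epithelium. Groups were taken from the genotype label: 5 arrays were Villin-Gremlin and 6 were wild type. The design text speaks of equal groups, and the 11 arrays with labels were analysed here. No label states that each array held RNA of a separate mouse, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy micro kit with DNase treatment, checked on a Bioanalyser, and turned into biotinylated cRNA with an Ambion MessageAmp kit.

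The deposited signal table gives, per the file headers, a mean bead signal and a detection p-value for 45281 probes on each array. The signals are intensity values on a linear scale, and per the file headers and the deposited values they were neither background-subtracted nor normalized, the lowest on any array being 119. The detection p-values, per the deposited values, run in steps of 1 in 936. A second table holds the authors' processed log2 values of the same arrays. Its normalization is not given in the sources used here. Set against the log2 signals of the same probes, each column matched its own array best (correlation 0.985 to 0.992 across probes), the slope over bright probes was 1.03 to 1.05, and the column medians were 5.04 to 5.13. Its scale is therefore log2 with no centring by gene, and only the background step and the method of normalization stay unknown.

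Probes were named through the platform's annotation table: 34885 carried 1 gene symbol, 18 several and 10378 none. Entrez identifiers matched 34807 of the named probes to a current gene table, 0 symbols changed, and 19057 genes were named. Of 589 genes on the lists fixed in advance, 529 had a named probe. No coordinates are given because the array table names no genome build.

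Signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3: a normal-exponential model whose background was estimated from the detection p-values, an offset of 16, log2 transformation and quantile normalization. Probes with a detection p under 0.01 on at least 5 arrays were kept, which left 14203 probes and 8234 named genes. A gene with several kept probes was represented by the probe with the highest mean over all 11 arrays. Each gene was fitted with lmFit and eBayes of limma, Villin-Gremlin against wild type with no covariate, and p-values were adjusted by Benjamini-Hochberg. A gene counted as changed at an adjusted p under 0.05. Log2 fold changes are Villin-Gremlin minus wild type, with the standard error (SE) of the fit. Where no probe of a gene rose above background on any array of a group, the fold is a bound ("at least"): the mean of the brighter group over the mean, per array, of the higher of that gene's value and the lowest value among detected probes. The number of arrays limits the precision. In simulated data with each gene's real spread and independent noise, 200 genes among 8234 were changed. The G2 and mitosis genes outside these 200 were shifted by a log2 of 1 as well. Among the 200, the fit recovered 31.3%, 65.7% and 95.5% of changes of log2 size 0.5, 1 and 2. Of its 140 calls 6 were false. Real genes are correlated and far more of them changed, so these rates need not hold for the real fit.

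Before the data were examined, 37 gene lists for pathways and for cell types that villi hold or could carry over were fixed, together with the design, the alternatives and the rule for named genes. The 29 lists with at least 3 measured members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation, fry of limma and a two-sided exact permutation test of the list mean per array, over all 462 splits of the arrays into 5 and 6, stood beside it. The smallest p that this permutation can give is 0.00216. The named genes were Grem1, the 12 largest increases and the 12 largest decreases among changed genes whose groups did not overlap, up to 4 members with the smallest p of each list past the camera threshold, and the 2 members with the smallest p of the BMP target, Wnt target, crypt stem cell and both cell cycle lists. Other genes are named as members of the fixed lists, or in the closing section after their values were seen.

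The alternatives were no background correction, an offset of 50, median scaling, the authors' log2 values, no detection filter, detection on all arrays, the mean of a gene's probes, array weights, a trended and robust variance prior, the replicate number as a block, and each array left out in turn. Added after the data were seen were the fit without Villin-Gremlin 5 and wild type 1, which lay apart from their groups on the second principal component, a block by the numbers of the column names, the sex of the mouse read from Y-linked genes, and the column position in the signal table. Lists of hypoxia targets, gut hormones, acinar genes and islet hormones were also added then. The block by column numbers left out wild type 1, whose column name holds no number. Slide as a block was not run, because no slide is named in the sources used here. Figures were drawn with matplotlib 3.10.9.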

Results

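Total RNA of small intestinal villi was profiled on 11 Illumina bead arrays, 5 from Villin-Gremlin mice and 6 from wild type mice of the same strain and age. The question named by the series is how expression in villi differs when Gremlin, which binds BMPs outside the cell and keeps them from their receptors, is made by the intestinal epithelium. Median raw signal per array ran from 157 to 207, and 13536 to 14808 of 45281 probes were above background on each array. The first principal component took 53.3% of the variance and placed all Villin-Gremlin arrays on one side and all wild type arrays on the other. Arrays Villin-Gremlin 5 and wild type 1 lay apart from their groups on the second component, at -27.83 and -27.85. Y-linked genes marked 1 array of each group as male.

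Grem1, the gene of the transgene product, had the largest fitted increase, and the BMP target genes measured on the arrays fell together. The Grem1 probe read 13.95 ± 0.14 (log2, SD, n = 5) in Villin-Gremlin villi and 6.10 ± 1.51 (SD, n = 6) in wild type villi, a 229-fold difference (log2 fold change 7.84 ± 0.57 SE, limma adjusted p = 1.46e-06). It was above background on 5 of 5 Villin-Gremlin arrays and on 2 of 6 wild type arrays, with wild type 5 highest of these at 8.99. Without background correction the log2 fold change was 6.01. Whether the probe lies within the transgene is not given in the sources used here.

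All 4 measured BMP target genes fell, of 11 on the list, and all 4 also passed when adjusted over the list alone. Id1, Id2 and Id3, which encode inhibitors of basic helix-loop-helix transcription factors, changed by -2.57 ± 0.25, -2.94 ± 0.19 and -2.17 ± 0.15 (log2, SE; limma adjusted p = 1.27e-05, 6.47e-07 and 8.75e-07). Smad6, an inhibitor of BMP signalling that the pathway itself induces, was above background on 0 of 5 Villin-Gremlin arrays and was at least 2.80-fold lower (limma adjusted p = 6.27e-07). The median change of the list was -2.37, with camera adjusted p = 2.64e-06, adjusted p = 0.0679 with an estimated correlation, and exact permutation p = 0.00216, and T cell markers fell by 1.93 ± 0.21 in the same villi. The 7 measured genes of BMP receptors and their Smads, among them Bmpr1a and Smad5, included 0 that passed the test (median 0.13, camera adjusted p = 0.836).

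**Figure D1:**
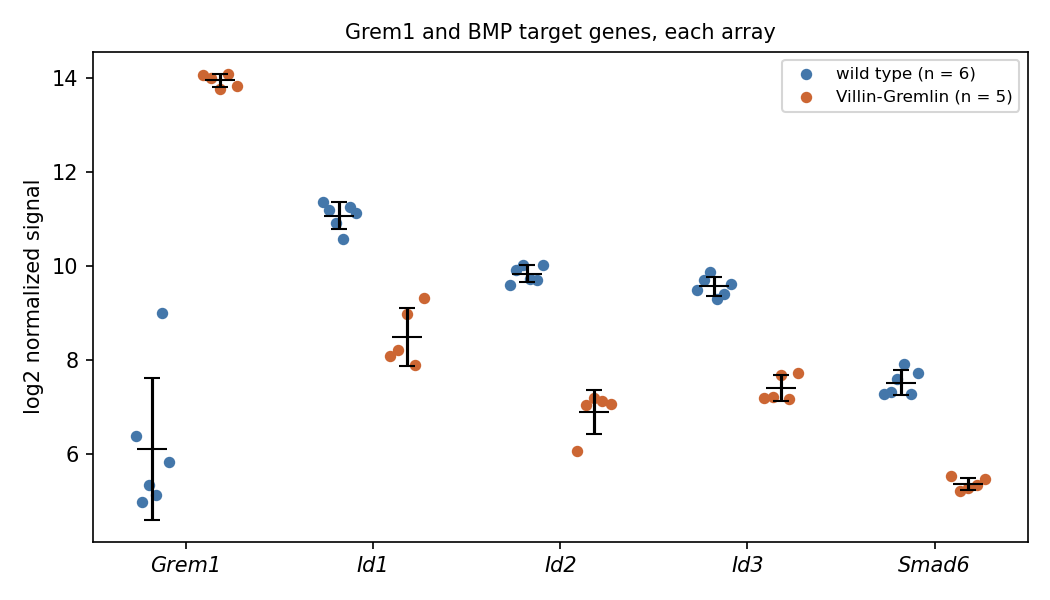
Log2 normalized signal of Grem1 and 4 BMP target genes on each array, wild type (blue, n = 6) and Villin-Gremlin (orange, n = 5); each point is an array, and black bars give the mean and SD. Grem1 is near 14 on the Villin-Gremlin arrays, with wild type 5 at 8.99, and the target genes of the groups do not overlap.

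With these genes included, 2792 of 8234 tested genes changed (limma, Benjamini-Hochberg), 1476 higher and 1316 lower in Villin-Gremlin villi (919 higher and 1217 lower with median scaling), and 833 changed at least 2-fold, 386 higher and 447 lower. Cldn2, a claudin that forms cation-selective pores in tight junctions, rose 20.6-fold (log2 fold change 4.37 ± 0.37 SE, adjusted p = 4.83e-06). Cybrd1, the ferric reductase of the duodenal brush border, was above background on 0 of 6 wild type arrays and was at least 6.67-fold higher (adjusted p = 2.78e-04), and Slc11a2, the iron importer DMT1, rose 10.8-fold (3.43 ± 0.45, adjusted p = 1.21e-04). Cybrd1 read 10.63 and 10.71 on Villin-Gremlin 3 and 5, and 7.18 to 7.94 on the other Villin-Gremlin arrays. Of the 3 kept probes of Slc11a2, 2 rose and 1 differed by 0.11 ± 0.18. Akr1b8, an aldo-keto reductase, rose 15.1-fold, and Capg, an actin-capping protein, 10.99-fold. Bmp3, an atypical member of the BMP family, rose 9.89-fold, and Ddah1, which breaks down asymmetric dimethylarginine, was at least 5.50-fold higher. The sugar transporter Slc2a6, Mboat1, Prss27 and the sulfotransferase Sult1c2 completed the increases named by the rule, at 10.9, 10.8, 10.5 and 9.75-fold. Akr1b8 and Bmp3 were above background on 2 of 6 wild type arrays, Slc2a6 and Prss27 on 1 of 6, and Sult1c2 on 3 of 6. Sult1c2 read 11.75 on Villin-Gremlin 5 and 7.57 to 9.26 on the other Villin-Gremlin arrays.

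The representative probe of Slc5a12, a sodium-coupled lactate transporter, read 11.49 ± 0.42 (SD, n = 6) in wild type villi and was not above background on any of the 5 Villin-Gremlin arrays (limma adjusted p = 1.77e-10), while its other kept probe differed by -0.35 ± 0.20 (adjusted p = 0.197 over probes). Dnase1 was 37.2-fold lower (log2 fold change -5.22 ± 0.47 SE, adjusted p = 7.17e-06). Susd2 was at least 17.1-fold lower, and Enpp7, the alkaline sphingomyelinase, was 29.5-fold lower and above background on 1 of 5 Villin-Gremlin arrays. Nt5e, which makes adenosine from AMP at the cell surface, was 15.9-fold lower (-3.99 ± 0.47), and the nucleoside transporter genes Slc28a2 and Slc28a2b were 12.6 and 12.8-fold lower; probes of these close paralogs could share signal. Cyp2b23 and Cyp3a11, which encode cytochromes of drug metabolism, were 14.5 and 12.2-fold lower. Cubn, the receptor for intrinsic factor and vitamin B12, was 13.8-fold lower and above background on 2 of 5 Villin-Gremlin arrays. Aldh4a1, of proline breakdown, was 12.6-fold lower, and Oas1d at least 6.47-fold lower.

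Sizes depended on background correction. Without it, 26 of 55 named genes other than Grem1 and those with a bound had log2 fold changes more than 1.5 times smaller, among them Akr1b8, Slc2a6, Prss27, Bmp3 and Sult1c2 (2.20, 1.75, 1.66, 1.88 and 1.86) and Enpp7 and Cubn (-2.84 and -2.28). The count of genes changed at least 2-fold was 346 without background correction and 510 among probes detected on all arrays. Among changed genes, 32 were not above background in wild type and 65 not in Villin-Gremlin villi, and 5 had probes called in opposite directions.

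**Figure D2:**
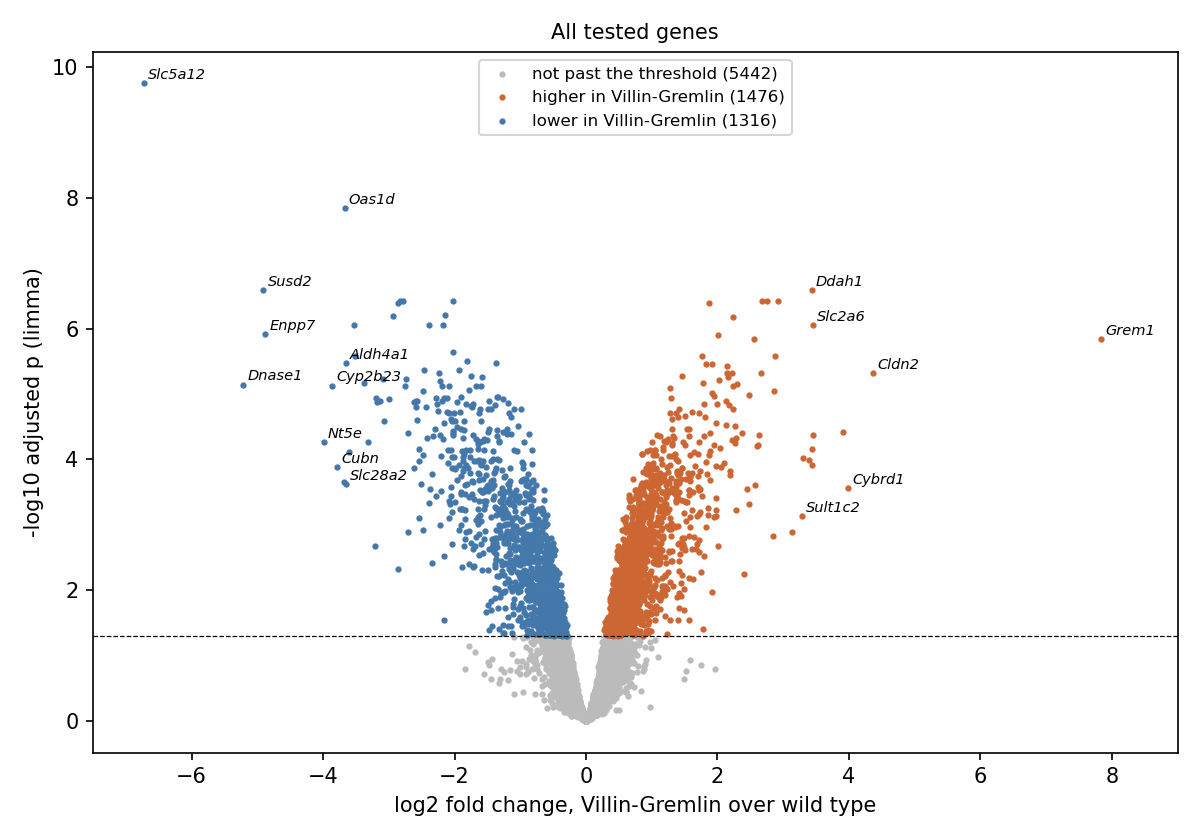
Log2 fold change (x axis, Villin-Gremlin over wild type) against -log10 limma adjusted p (y axis) for each of 8234 genes, with 1476 higher genes in orange, 1316 lower genes in blue and the threshold dashed. Some of the named genes of largest change carry labels; for genes below background in a group the position shows the fitted value, not a bound.

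Of 29 gene lists tested, 9 passed the camera threshold, 3 higher and 6 lower in Villin-Gremlin villi. None passed with an estimated correlation (lowest adjusted p = 0.0679; 4 lists at an unadjusted p under 0.05), 13 passed by fry and 15 by exact permutation. In 31 of 100 splits of the arrays into 5 and 6, camera at the preset correlation called as many lists. Splits uneven in genotype carry part of the genotype difference, so this is not a rate under chance alone. The exact permutation p is given beside each list past the camera threshold. It compares list means between the groups and not with other genes. For 8 of the 9 lists the list means of the groups did not overlap.

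Genes of the villus tip, where the oldest enterocytes sit, and of the brush border were lower in Villin-Gremlin villi. Of 12 measured villus tip genes 8 fell and 0 rose (9 fell when adjusted over the list alone), among them Nt5e, Slc28a2, Ada at 9.98-fold lower (-3.32 ± 0.39, limma adjusted p = 5.45e-05) and Enpp3 at 6.03-fold lower (-2.59 ± 0.25). Apoa4, which carries lipid out of the villus tip, differed by -0.13. The median change was -1.02, with camera adjusted p = 2.61e-05, adjusted p = 0.304 with an estimated correlation, and exact permutation p = 0.00216. Of 25 brush border digestion and transport genes 19 fell and 0 rose, the same count when adjusted over the list alone. Slc6a19, the main neutral amino acid transporter, changed by -1.59 ± 0.14, the peptidase Dpp4 by -1.39 ± 0.14 and the glucose transporter Slc5a1 by -0.93 ± 0.13 (limma adjusted p = 5.47e-06, 1.47e-05 and 2.06e-04). Lactase (Lct) fell by 2.06 on the log2 scale, while sucrase-isomaltase (Sis) differed by -0.33 and alkaline phosphatase (Alpi) by 0.34, and neither passed the test. The list's median was -1.001, with camera adjusted p = 5.70e-08, adjusted p = 0.235 with an estimated correlation, and exact permutation p = 0.00216. Along with both lists, T cell and intraepithelial lymphocyte markers fell by 1.93 ± 0.21 in the list mean.

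**Figure D3:**
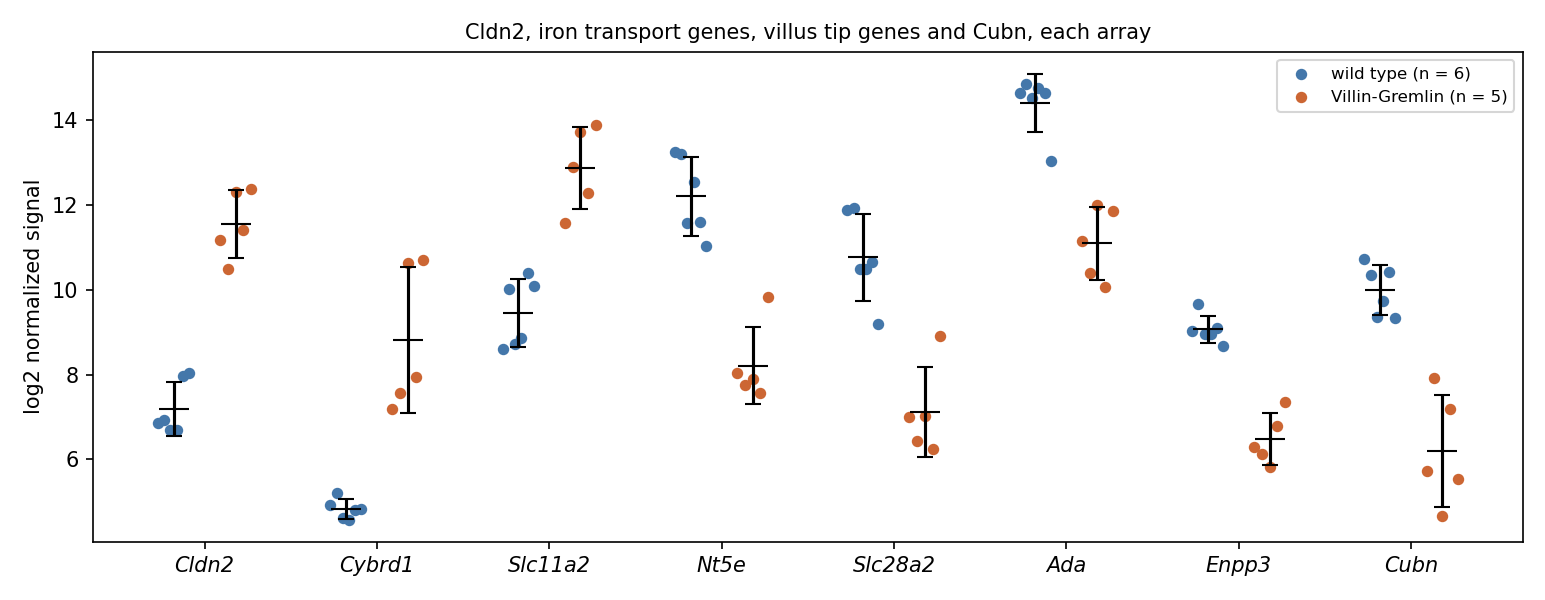
Log2 normalized signal on each array for Cldn2, the iron uptake genes Cybrd1 and Slc11a2, the villus tip genes Nt5e, Slc28a2, Ada and Enpp3, and Cubn, in wild type (blue, n = 6) and Villin-Gremlin villi (orange, n = 5); points are arrays, bars the mean and SD. The groups do not overlap for any of these genes, and Nt5e was highest among Villin-Gremlin arrays on Villin-Gremlin 5, at 9.82.

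Genes of cell division rose in the villi. Of 17 measured G2 and mitosis genes 15 rose and 0 fell (16 rose when adjusted over the list alone). Cdca8 and Bub1b, of the chromosomal passenger complex and the spindle checkpoint, rose 2.48 and 2.25-fold, the topoisomerase Top2a 2.33-fold and the kinesin Kif23 2.81-fold (limma adjusted p = 8.95e-05, 6.73e-04, 3.77e-04 and 4.27e-04). Top2a was above background on 3 of 6 wild type arrays, and 1 of 3 kept Kif23 probes differed by -0.02. Without background correction Cdca8, Bub1b, Top2a and Kif23 rose by 0.66, 0.53, 0.48 and 1.15 on the log2 scale. The median change was 1.07, with camera adjusted p = 3.24e-07, adjusted p = 0.281 with an estimated correlation, and exact permutation p = 0.00433. Cytosolic ribosomal protein genes rose in 15 of 15 measured members, 15 also when adjusted over the list alone, with Rps6 2.34-fold, Rpl4 2.22-fold, Rplp0 2.18-fold and Rps9 1.99-fold higher (median 0.90, camera adjusted p = 1.83e-08, adjusted p = 0.235 with an estimated correlation, exact permutation p = 0.00216). The Rplp0 probe was dim, at 6.75 in wild type and 7.87 in Villin-Gremlin villi, and rose by 0.56 on the log2 scale without background correction. In the same villi the T cell marker list fell by 1.93 ± 0.21.

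S phase genes were mixed: of 18 measured, 8 rose and 2 fell (9 and 2 when adjusted over the list alone). The thymidylate synthase gene Tyms rose 2.96-fold, and the cyclin gene Ccne2, above background on 0 of 5 Villin-Gremlin arrays, was at least 1.68-fold lower. The list missed the threshold (median 0.46, camera adjusted p = 0.0564, exact permutation p = 0.0152). With all arrays it passed with median scaling (adjusted p = 0.0190), in the authors' log2 values (0.0319), with no detection filter (0.00204), with probes detected on all arrays (0.0231) and with sex (0.0494) or column position (0.0475) as a covariate. It also passed without Villin-Gremlin 4 (adjusted p = 0.0388), and without wild type 1, 2, 3, 4, 5 or 6 (adjusted p = 0.0316, 0.0260, 0.0273, 0.0130, 0.0195 and 0.0494). Of 10 crypt stem cell markers 6 rose, among them Lrig1 at 2.43-fold, Prom1 and Sox9, while Axin2, a feedback inhibitor and target of Wnt signalling, was 3.59-fold lower (-1.84 ± 0.31, limma adjusted p = 5.96e-04) and Olfm4 differed by -0.01. The stem cell list gave camera adjusted p = 0.0761 and exact permutation p = 0.00866, and it passed camera with median scaling (adjusted p = 0.0204), without Villin-Gremlin 5 (0.0292) and without Villin-Gremlin 5 and wild type 1 (0.0432). Of 6 Wnt target genes 2 rose, Sox9 and the cyclin gene Ccnd1 at 3.23-fold, and 1 fell, Axin2 (camera adjusted p = 0.948). Of 5 Notch pathway genes 2 rose, Hes1 by 1.20 and Hes6 by 0.55 on the log2 scale (camera adjusted p = 0.490).

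Genes of cholesterol synthesis rose: 13 of 17 measured members were higher and 0 lower, with the same counts adjusted over the list alone. Cyp51, the sterol demethylase, rose 7.26-fold (2.86 ± 0.26, limma adjusted p = 9.01e-06), Lss, which closes the sterol rings, 4.82-fold, Mvd 4.55-fold and Idi1, of the isoprenoid steps, 2.78-fold. A dim second probe of Lss differed by -0.19. The list's median was 1.12, with camera adjusted p = 7.37e-07, adjusted p = 0.235 with an estimated correlation, and exact permutation p = 0.00216, while T cell markers fell by 1.93 ± 0.21. Lipid absorption and lipoprotein genes went both ways: 5 of 18 fell, with the fatty acid transport protein gene Slc27a4 at -1.81 and the cholesterol importer Npc1l1 at -1.28, and 3 rose, Acadl, Plin2 and Ppara (7 fell when adjusted over the list alone). That list gave camera adjusted p = 0.0818 and exact permutation p = 0.00216, and it passed camera with no detection filter (adjusted p = 0.0192) and with probes detected on all arrays (0.0304). Of 17 xenobiotic metabolism genes 4 fell, among them Cyp3a11 and Cyp2b10 (-3.37), and 3 rose, among them Gsta4 (2.10), with camera adjusted p = 0.238. Respiratory chain genes stayed close to 0, with a median of 0.02, 1 of 17 members past the test and camera adjusted p = 0.940.

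T cell and intraepithelial lymphocyte markers were the lists' strongest decrease by camera p, and 11 of 12 measured members fell (11 when adjusted over the list alone). Cd3g, of the T cell receptor complex, was 4.77-fold lower (-2.26 ± 0.23), its signalling kinase Zap70 4.59-fold, and Klrd1 and Nkg7, of cytotoxic lymphocytes, both 4.48-fold lower (limma adjusted p = 1.84e-05, 1.29e-05, 1.16e-05 and 2.77e-05). The exception, Cd8b1, differed by -0.02 ± 0.12. The median was -2.10, with camera adjusted p = 5.20e-09, adjusted p = 0.235 with an estimated correlation, and exact permutation p = 0.00216. Of 4 macrophage and dendritic cell markers 2 fell, Fcer1g by 2.10 and Tyrobp by 1.04 on the log2 scale (camera adjusted p = 0.0564, exact permutation p = 0.00216); the list passed camera without Villin-Gremlin 3 (adjusted p = 0.0463), Villin-Gremlin 5 (0.0313), wild type 5 (0.0430) or Villin-Gremlin 5 and wild type 1 together (0.0432), and with median scaling (0.0405), no detection filter (0.00204), array weights (0.0360) or column position (0.0475).

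Interferon response genes were lower as a list, with 5 of 19 members down and 0 up, the same adjusted over the list alone. Gbp2, Gbp3 and Igtp, which encode interferon-induced GTPases, were 4.20, 2.63 and 3.10-fold lower and the transcription factor Irf7 1.93-fold lower. The list gave camera adjusted p = 0.0227, adjusted p = 0.636 with an estimated correlation, and exact permutation p = 0.0433, and its list means overlapped between the groups. It was lost without Villin-Gremlin 2 (adjusted p = 0.0670), wild type 1 (0.0708) or wild type 3 (0.0505), by fry (0.0602) and by permutation after adjustment (0.0697). The T cell markers of these villi fell by 1.93 ± 0.21. The 7 MHC class II genes had a median of -1.29, from -1.84 to -0.68 with 1 array left out, and 0 passed the test (camera adjusted p = 0.0975). That list passed without Villin-Gremlin 3 (adjusted p = 0.0107), Villin-Gremlin 5 (0.0479) or wild type 2 (0.0470), and with no detection filter (0.0435), array weights (0.0360) or column position (0.0480).

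Among secretory cell types, tuft cell markers fell in 4 of 7 measured members (4 adjusted over the list alone): Sh2d6 was 2.47-fold lower, Ltc4s and Alox5ap, of leukotriene synthesis, 1.83 and 1.49-fold, and the kinase Dclk1 1.73-fold lower. Without background correction Sh2d6, Ltc4s, Alox5ap and Dclk1 changed by -0.62, -0.57, -0.33 and -0.38 on the log2 scale. The tuft cell list gave a median of -0.58, camera adjusted p = 0.0446, adjusted p = 0.235 with an estimated correlation, and exact permutation p = 0.00216. Its call was lost without Villin-Gremlin 2 (adjusted p = 0.0670), wild type 3 (0.0546) or wild type 6 (0.0502), with median scaling (0.0556) and in the authors' log2 values (0.0582), and Alox5ap lost its own call without wild type 3 (0.0582). Alongside, the T cell markers fell by 1.93 ± 0.21. Of 14 goblet cell markers 3 rose, Spink4, Agr2 and Klk1, and 3 fell, Clca1, Guca2a and Sytl2 (camera adjusted p = 0.940). Of 15 enteroendocrine markers 3 rose, the hormone genes Gcg and Tac1 and the lectin gene Reg4, and 3 fell, Sct, Nts and Isl1 (camera adjusted p = 0.981). Paneth cell markers had 0 of 9 members past the test, a median of -0.35 (0.04 without Villin-Gremlin 5) and camera adjusted p = 0.494. In 6 of the 29 lists the sign of the median turned when 1 array was left out: the Paneth, enteroendocrine, Wnt target, respiratory chain, proximal and regenerative lists.

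The remaining lists did not pass camera. Proximal small intestine markers split, with Cybrd1, Slc11a2 and the iron exporter gene Slc40a1 (8.80-fold) up and Lct and Heph down (camera adjusted p = 0.477, exact permutation p = 0.00216). Of 3 distal markers Cubn and Slc51b fell (camera adjusted p = 0.0761, exact permutation p = 0.00216). Of 8 lower villus antimicrobial genes Lypd8 and Nlrp6 rose, and Reg3b and Reg3g differed by 0.00 and -0.04 (camera adjusted p = 0.238, exact permutation p = 0.0173, 0.0335 after adjustment). Immediate early and heat shock genes had 6 of 12 members down, led by Jun (-1.72), and 2 up, Egr1 and Hsph1 (camera adjusted p = 0.114); that list passed without Villin-Gremlin 5 (adjusted p = 0.0292) and with column position (0.0475). Regenerative genes had Krt7 and Anxa3 up and Il33 down (camera adjusted p = 0.836). Smooth muscle and fibroblast markers, at -0.88 ± 0.54 and -0.85 ± 0.68 in the list mean (-0.54 and -0.48 without wild type 1), had 0 members past the test (camera adjusted p = 0.192 and 0.490). Lists of gastric, colonic, endothelial, B cell, mast cell and neutrophil, nerve, red blood cell and exocrine pancreas genes had fewer than 3 measured members and were not tested.

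**Figure D4:**
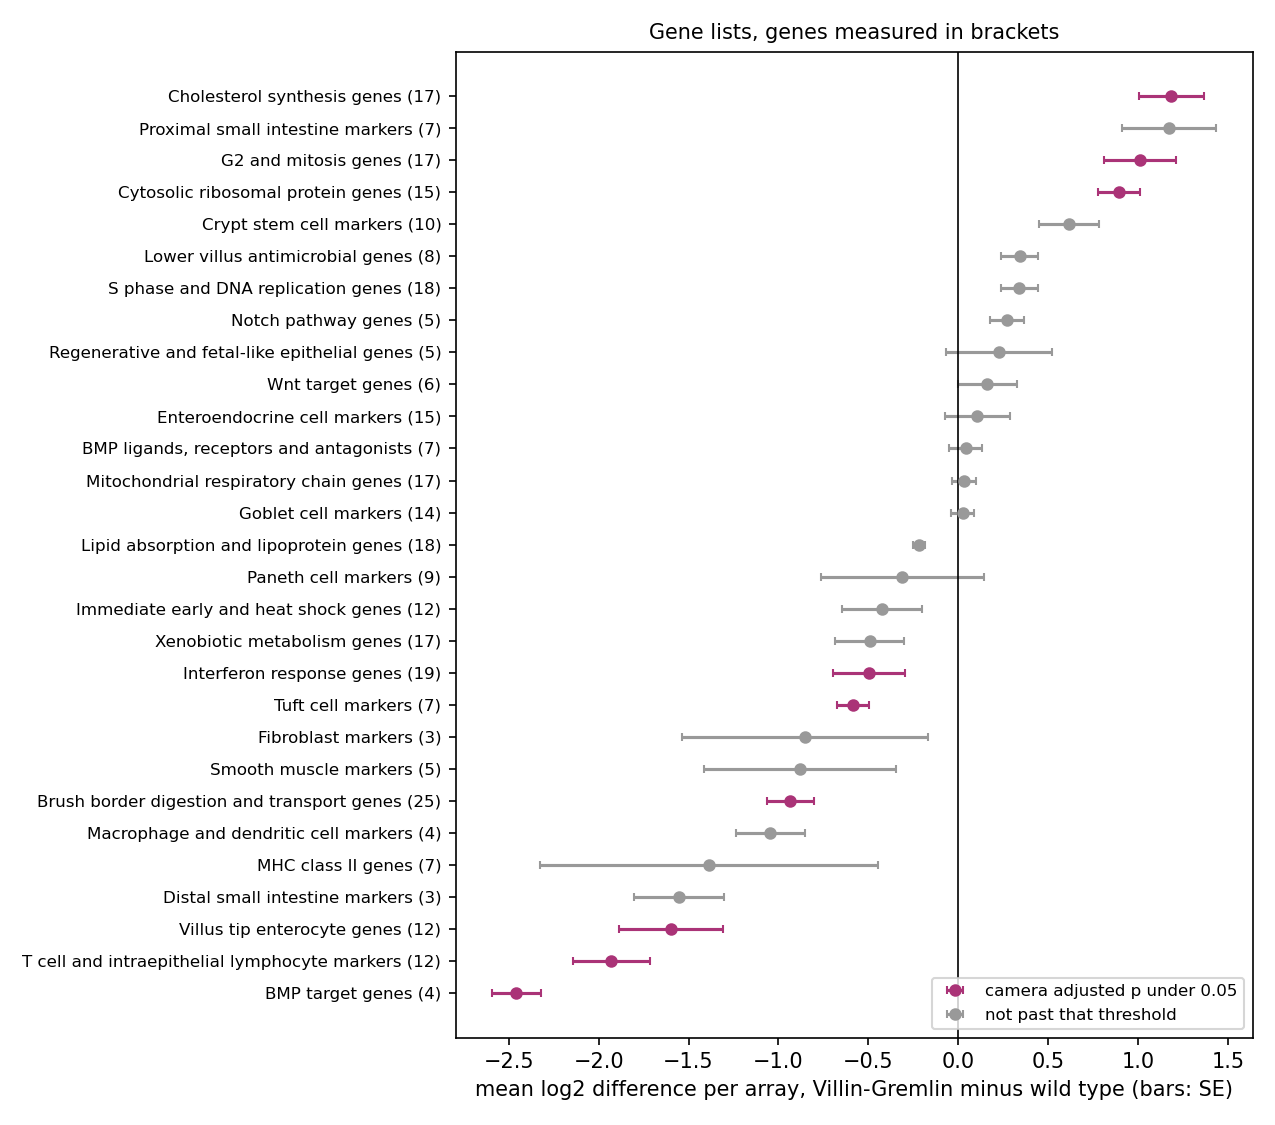
Difference in list mean, Villin-Gremlin minus wild type (x axis, log2), for each of the 29 tested gene lists (y axis, measured genes in brackets); points are differences between the group means, bars the SE over 5 and 6 arrays, and purple marks the 9 lists past the camera threshold. BMP target genes lie lowest, at -2.46, and cholesterol synthesis genes highest, at 1.18.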

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

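The tests of whole crypts and of a more proximal stretch of gut, and the values that decided the latter, were chosen after the values had been seen, as was the level that decided the test of islet genes; the other tests were set before their results. Of 186 groups of values, 11 had 1 array set apart from the rest of its group, and chance alone sets apart about 1 in 20 (4.78% and 5.11% of simulated groups of 5 and 6 arrays).

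Grem1 read 8.99 on wild type 5, against 4.98 to 6.37 on the other wild type arrays. Slc2a6 was high on wild type 2 (6.42, the others 5.23 to 5.67) and Susd2 on wild type 1 (11.39, the others 9.62 to 10.23). Villin-Gremlin 5 was set apart for Bmp3 (7.58, the others 9.45 to 10.20), Nt5e (9.82, the others 7.56 to 8.04) and Alox5ap (6.80, the others 7.61 to 7.86). Id2 was low on Villin-Gremlin 1 (6.05, the others 7.03 to 7.18), Zap70 high on Villin-Gremlin 3 (7.23, the others 6.32 to 6.58) and Ada low on wild type 6 (13.05, the others 14.53 to 14.87). The mean of the xenobiotic metabolism list was low on wild type 1 (10.84, the others 11.34 to 11.62), and that of the respiratory chain list on Villin-Gremlin 5 (13.57, the others 13.76 to 13.83). Among 1922 kept probes without a single gene name, which no comparison used, 592 changed (limma, Benjamini-Hochberg), 360 higher and 232 lower.

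G2 and mitosis genes were higher in Villin-Gremlin villi by 1.01 ± 0.20 (log2, SE, exact permutation p = 0.00433). Villus preparations could carry crypts, where cells divide. The Paneth cell genes Lyz1 and Defa20 were above background on every array. Lyz1 read 13.54 in wild type and 13.77 in Villin-Gremlin villi, and Defa20 13.84 and 13.45, so both groups held Paneth cell RNA. Whether probes this bright can still show a rise was not tested. Whole crypts would bring Paneth cells, whose markers differed by -0.31 ± 0.45 (exact permutation p = 0.535), and by 0.06 ± 0.29 without Villin-Gremlin 5, so the change of the mitosis list exceeded that of the Paneth list by 1.32 ± 0.36 (exact permutation p = 0.00216). Without Villin-Gremlin 5, the array with the lowest Paneth signal, the excess was 1.02 ± 0.22 (exact permutation p = 0.00476, the smallest that 10 arrays allow). Crypt stem cell markers rose by 0.62 ± 0.17 (exact permutation p = 0.00866), which goes with crypts, although Olfm4 differed by -0.01 and Axin2 fell. The contrast was set up after both changes had been seen, so its p-values add no support. As far as such bright Paneth probes can still rise, the Paneth markers showed no gain to match that of the mitosis list. More whole crypts are not excluded by this. A carry-over of the upper crypt, or of crypts with fewer Paneth cells, stays open. So does division within the villus epithelium under the transgene, which was not tested.

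Cybrd1 was at least 6.67-fold higher, Slc11a2 and Slc40a1 were higher by 3.43 and 3.14 on the log2 scale, and as genes of the proximal gut they could mark a more proximal sample. The rise was uneven: Cybrd1 read 10.63 and 10.71 on Villin-Gremlin 3 and 5, and 7.18 to 7.94 on the other Villin-Gremlin arrays. The same 2 arrays were highest for Slc11a2 (13.73 and 13.90) and in the mean of the proximal list (11.73 and 12.30). Hormone genes of the proximal gut moved against those of the distal gut by -0.73 ± 0.21 (exact permutation p = 0.0173). Within that contrast the distal genes went both ways, with Gcg up by 1.41 and Nts down by 1.37, and the proximal gene Sct fell by 1.15. Gata4, a proximal factor, differed by -0.10 ± 0.20 and lactase fell, while the distal marker list fell by 1.55 ± 0.25 in the list mean (exact permutation p = 0.00216). A more proximal sample and an effect of the genotype on Cybrd1, Slc11a2 and Slc40a1 cannot be told apart, since the values go both ways and the labels name no gut segment. All 3 genes are known targets of hypoxia-inducible factor 2. A set of 12 measured hypoxia targets not looked at before was higher by 0.44 ± 0.07 in the list mean (exact permutation p = 0.00216). That was the result set in advance for hypoxia-inducible transcription, but the permutation compares the set between the groups and not with other genes. With 15 of 29 lists past the same test after adjustment, it does not single out these targets. The set held hypoxia targets in general, so it does not bear on factor 2 in particular. Of its members 6 rose and 2 fell, Mxi1 (-0.83) and Slc2a3. The mean of the set rested largely on Pfkl, Aldoa and Ddit4 (1.87, 1.77 and 2.05), while Kdm3a, Pgam1 and Pgk1 rose by 0.60, 0.54 and 0.54. Its members Ldha, Tpi1, Pfkfb4 and Egln1 differed by 0.11, 0.01, -0.38 and 0.34 and did not pass the test. Vegfa was lower by its representative probe (-0.44), several of the targets are also glycolytic genes that growth can raise, and iron status and the genotype itself were not tested.

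Exocrine pancreas genes appeared on Villin-Gremlin 5: of 9 named on the array, 7 were above background there and on no other array, among them Cela2a at 10.52 (5.62 or less elsewhere), Try4 at 9.15 and Ctrb1 at 9.02. Among 10 further acinar genes above background on any array, 70% were highest on Villin-Gremlin 5, led by Amy2a5 at 12.56 (8.07 or less elsewhere), against 13.95% of all probes above background on any array, but this fell short of the 75% set as the mark for carried-over pancreas. Of the 7 highest there, 4 were above background on no other array, and the tissue itself makes some of the 10: Spink1, Rnase1 and Pnliprp2 were above background on all 11 arrays and highest on others. For pancreas tissue carried over, islet part, 0 of 3 islet hormone genes were above background, which decides nothing, since islet cells are a small part of the pancreas and the median exocrine gene read only 9.02. Pancreas tissue in this preparation and acinar genes made in its mucosa cannot be told apart, and without this array 2736 genes changed, 777 of them at least 2-fold, and 13 lists passed camera.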

How the results depend on the processing

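The fits without Villin-Gremlin 5 and wild type 1 together, with a replicate block by column number, with sex as a covariate and with column position as a covariate were chosen after the data were seen. Across the settings with all arrays, genes changed ran from 2136 (median scaling) to 3040 (array weights), against 2792, and without Villin-Gremlin 5 and wild type 1 they numbered 2664, with 749 changed at least 2-fold. The count of genes changed at least 2-fold, 833, was 346 without background correction, where the cause was not tested, and 510 with probes detected on all arrays, where fewer genes were tested. Of 29 lists tested, 9 passed by camera at the preset correlation, 0 by camera with an estimated correlation and 15 by exact permutation. With the replicate block, which also leaves out wild type 6, 14 passed, against 9 when only wild type 6 was left out. The cause of this rise was not tested. Leaving out each array in turn gave 2334 to 2736 genes, 745 to 876 at least 2-fold, 7 to 13 lists, and a Grem1 log2 fold change of 7.62 to 8.41, the highest without wild type 5. The Grem1 change was 6.01 without background correction and had no value with probes detected on all arrays. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.00, 0.11, -0.20, 0.05 and -0.16 across genes, and 1 of 5 Villin-Gremlin arrays matched its own number best. With the replicate block, which leaves out wild type 6, 2207 genes changed, 864 at least 2-fold, and Grem1 by 7.78. The stem cell, S phase, smooth muscle, macrophage and MHC class II lists gained a call there. The S phase list also gained one without wild type 6 and with no block (camera adjusted p = 0.0494). The columns of the signal table carry other numbers than the titles, with Villin-Gremlin 1 beside wild type 2 and so on, and these did not pair the samples either: the correlations were -0.15, 0.08, 0.05, 0.10 and -0.15, and 0 of 5 arrays matched their own number best. With that replicate block, which leaves out wild type 1, 2319 genes changed, 788 at least 2-fold, 10 lists passed and Grem1 changed by 7.89. Interferon response genes lost their call (camera adjusted p = 0.0994), and S phase and macrophage genes gained one. Without wild type 1 and with no block, interferon response genes also lost their call (camera adjusted p = 0.0708) and S phase genes gained one (0.0316). Median scaling split the lists 5 higher and 6 lower and the authors' log2 values 4 and 5, against 3 and 6, while the share of higher genes was 43.0% with median scaling, against 52.9%. Of 1488 values of the other named genes under these settings, 1484 kept direction and call, 4 lost the call and 0 reversed: Alox5ap with no detection filter, with column position and without wild type 3 (adjusted p = 0.0501, 0.0519 and 0.0582), and Slc5a12 with probes detected on all arrays, which take its other probe. Of 808 list values, 735 kept their call, 53 gained one, 20 lost one and 0 reversed. Genes whose signal lies below background in one group have only a bound.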

Other observations

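The genes and families below were chosen after their values were seen. The aquaporin genes Aqp1, Aqp3 and Aqp7 changed by -3.17 ± 0.31, -3.51 ± 0.27 and -3.19 ± 0.30 (log2, SE; limma adjusted p = 1.32e-05, 2.60e-06 and 1.16e-05), and Aqp3 was above background on 2 of 5 Villin-Gremlin arrays, while Aqp4, Aqp8 and Aqp11 differed by 0.73, 0.28 and -0.14 and did not pass the test. Within the BMP family, Bmp3 rose while Bmp8a fell by 3.52 ± 0.24 (limma adjusted p = 8.75e-07) and Bmp8b was at least 1.45-fold lower. Of genes picked singly, the glucose transporter Slc2a1 rose by 2.56 ± 0.19, the carbonic anhydrase Car9 by 2.88 ± 0.22 and Pdk1 by 1.83 ± 0.15. Egln3 rose by 1.00 ± 0.12 and the transferrin receptor Tfrc by 1.05 ± 0.28. From the set of hypoxia targets above, the glucose transporter Slc2a3 was at least 1.64-fold lower and the glycolytic genes Ldha and Tpi1 differed by 0.11 and 0.01. Of hormone genes picked singly, Tac1 and Gcg rose by 2.001 ± 0.20 and 1.41 ± 0.28, while Nts fell by 1.37 ± 0.29 and Sct fell by 1.15 ± 0.19, and Cck, Ghrl, Gip, Pyy and Sst did not pass the test. The goblet cell gene Spink4 rose by 1.42 ± 0.14.

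Grouped by symbol stem, 8 of 92 families with at least 10 measured genes passed camera at the preset correlation. For ribosomal proteins, 27 of 30 Rpl and 20 of 24 Rps genes of the cytosolic ribosome, and 20 of 44 Mrpl and 17 of 27 Mrps genes of the mitochondrial ribosome were higher, with 1 Mrpl gene lower (camera adjusted p = 4.90e-12, 3.63e-08, 4.17e-06 and 5.83e-06; adjusted p = 0.692, 0.692, 0.813 and 0.776 with an estimated correlation). Of 39 Eif genes of translation initiation 19 rose and 1 fell, and 10 of 16 Polr genes of RNA polymerases rose (camera adjusted p = 0.00241 and 0.00329; adjusted p = 0.640 and 0.692 with an estimated correlation). Cytochrome P450 (Cyp) genes fell in 15 of 26 cases and rose in 3, and Cd genes of surface antigens, many of them made by leukocytes, fell in 16 of 31 and rose in 3 (camera adjusted p = 0.00244 and 4.06e-04; adjusted p = 0.776 and 0.640 with an estimated correlation). All 8 kept the sign of their median under median scaling and in the authors' log2 values, although 9 Mrpl, 6 Mrps and 9 Eif genes rose under median scaling. T cell markers fell by 1.93 ± 0.21 in these villi.

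Chance as the source of the gene counts was tested with 100 splits of the arrays into 5 and 6. For genes changed, 1 of the 100 splits, the real one, gave as many as 2792, with 1 gene at most in the others. For genes changed at least 2-fold 1 of 100 gave as many as 833, with 1 at most in the others. The real split thus stood apart from the others drawn. Those mix the genotypes, which adds the genotype difference to the spread within groups. Their low counts therefore do not show how many genes chance would give. Whether the samples are separate mice also stays unknown. For gene lists changed, 31 of 100 splits gave 9 or more, with 14 at most, so chance is not excluded for the number of lists called by camera at the preset correlation. The split with 14 lists set Villin-Gremlin 5 and wild type 1, 2, 3 and 5 against the rest. A split as uneven in genotype as this carries part of the genotype difference, so 31 in 100 is not a rate under chance alone. The exact permutation p of each list compares its mean between the groups and not with other genes. With 2792 of 8234 genes changed, a list can pass it without standing out from the rest, and 15 of 29 lists passed. The proximal list, for one, had an exact permutation p of 0.00216 but a camera adjusted p of 0.477.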
